A study of Mus musculus with 18 samples.

How the data were processed

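RNA from 18 intestinal tumours of Apc Min mice was sequenced, 6 for each of 3 Macrod2 genotypes. Per the labels' protocols, tumours were resected at autopsy, total RNA was extracted with the AllPrep DNA/RNA Mini kit, and libraries were made with the TruSeq Stranded Total RNA kit, while the molecule field names polyA RNA. The deposited table holds counts, whole-number read counts for 24062 genes in each library, and the authors' RPKM values, reads scaled by gene length and library size. Per the submitters' processing notes the tools were Trimmomatic, TopHat and featureCounts of Subread 1.4.5-p1 with the mm10 genome. The strand setting of the counting and the options of these tools are not given in the sources used here, so the counts of genes that overlap on opposite strands are uncertain. In every library the deposited RPKM equalled the counts divided by gene length and library total, times the inverse of a TMM factor. All columns of values were matched to a sample by name.

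Groups came from the genotype and source labels. The titles number the mice within each genotype, so tumours were taken as separate animals. Libraries of 13529204 to 20857918 counts were compared in pairs by a chi-square statistic over genes with a summed count of at least 20, and the lowest value per degree of freedom was 20.3, so no library was a repeat of another. No batch is named in the labels. The first principal component of the 1000 most variable genes held 46.1% of the variance and gave no difference between genotypes past the threshold (exact permutation p of 0.710 for het against wt and 0.383 for hom against wt, n = 5 or 6). The second held 16% and gave an exact permutation p of 0.0303 for hom against wt, 0.364 after adjustment (n = 6). The median SD of log2 expression within a genotype was 0.357 in wt, 0.272 in het and 0.289 in hom.

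Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (14271), scaled by TMM factors and fitted with a robust quasi-likelihood model to the 17 large intestinal tumours. The contrasts were het against wt, hom against wt, hom against het and the mean of het and hom against wt, each with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Levels are CPM scaled by TMM factors over all 18 libraries. A list of 44 gene sets was fixed, and the 42 with at least 5 tested members entered camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists; posterior Hox genes and mitochondrially encoded genes were not tested. Camera was repeated with an estimated correlation, and fry tested each list by itself. The number of members past 0.05 was also counted adjusted over the list alone. The score of a list is the mean log2 CPM of its members relative to the mean of the 17 tumours.

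Genes were named by a fixed rule. Up to 10 genes per direction with the smallest p were named among those that passed, and where fewer than 5 passed, the 5 with the smallest p in that direction were given as values. Predicted genes and genes under a mean log2 CPM of 0 were excluded. To these came 15 fixed genes and up to 2 members per direction of each list past the threshold. The design, the lists, this rule and the first set of alternatives were fixed before the data were examined. Outside this rule, Flrt3, the genes of the site comparison, Slc10a2, Onecut2, Adora2b, Mcpt1, Reg3b, Tmem135, Rn45s, Lars2, Rpph1 and Rmrp were chosen after their values were seen, as were Timp3, Art3, Nudt5, Fosl1, Hsp90aa1, Hspa8 and Hsph1 in hom against wt, and Art3, Hist1h4c and Lct in carriers against wt.

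Gene positions on mm10 came from GENCODE for 22750 gene names, from RefSeq symbols for 227 and from RefSeq synonyms for 957, while 128 of the 24062 names had no single position. For chromosome imbalance, log2 CPM of 11976 autosomal genes with a mean of at least 1 were set against the mean of the 3 genotype means, and the median was taken for each of 19 autosomes (319 to 1029 genes each). Genotypes were compared by exact two-sided permutation tests, whose smallest possible p for 6 against 6 is 0.00216. The GC content was known for 95.5% of tested genes, and trends were removed with lowess curves of span 0.3.

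The scripts were tested on simulated counts with 200 of the genes changed. In simulated hom against wt 22.4% of genes changed 1.5-fold, 55.2% of genes changed 2-fold and 92.4% of genes changed 4-fold were recovered, with 4 false calls among 14271 genes. In simulated het against wt the shares were 14.9%, 70.1% and 92.4%, with 4 false calls, in hom against het 16.4%, 52.2% and 90.9%, with 3, and in carriers against wt 29.9%, 55.2% and 100%, with 3. Each gene was drawn by itself, without the correlation between genes of real tumours. These shares and false calls therefore check the scripts and do not give the error rates in the real tumours. A chromosome raised 1.5-fold (0.585 log2 units) was measured at 0.52, and 1 raised 1.1-fold (0.138) at 0.133.

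Alternatives covered RLE factors, no filter on low counts, all 18 tumours, the mouse number as a block, DESeq2 1.42.0, limma-voom with quality weights, limma on log2 of the deposited RPKM plus a pseudocount of 0.1 or 1 (genes with RPKM of at least 1 in at least 5 libraries), fits to the compared genotypes alone, a non-robust fit, a threshold of 0.10 and each tumour left out in turn. Added after the data were seen were fits without Rn45s, Lars2, Rpph1 and Rmrp, with the Gata4 level as a covariate, without wt 1 and wt 2, with 2 surrogate variables (sva 3.50.0) and with GC content and length trends removed. The Wilson interval of the Rn45s share and the floors, with 3 counts as the floor of a count of 0, cover counting error only. The interval of a fold change comes from the quasi-likelihood fit and includes the spread between tumours. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for tables and plots.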

Results

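Bulk RNA sequencing profiled intestinal tumours from male C57BL/6 mice that carry the Min allele of Apc, a truncating mutation of a negative regulator of Wnt signalling that gives mice many intestinal adenomas. The mice were wild type (wt), heterozygous (het) or homozygous (hom) for loss of Macrod2, which encodes a macrodomain enzyme that removes ADP-ribose from proteins. The titles of the libraries name 6 numbered mice of each genotype, with 1 tumour each. The source labels place 17 tumours in the large intestine and het 4 in the small intestine. This last tumour had no counterpart in the other genotypes and entered no comparison, which left 6 wt, 5 het and 6 hom tumours. Total gene counts ran from 13529204 in wt 4 to 20857918 in hom 1, and 16207 to 17154 genes had at least 1 count. In wt 3, Rn45s, the ribosomal RNA precursor, took 27.0% of the counts (95% Wilson interval 26.97% to 27.01%, counting error only), against 0.725% or less in each other tumour. The title of the series names chromosome instability and tumour growth, and its design text asks which transcripts differ between tumours by Macrod2 genotype.

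Macrod2 transcripts followed the genotype labels. In CPM, counts scaled by library size, wt tumours held 3.74 ± 0.605 (SD, n = 6), het tumours 2.20 ± 0.749 CPM (SD, n = 5) and hom tumours 0.158 ± 0.145 CPM (SD, n = 6). The het mean was 58.8% and the hom mean 4.23% of the wt mean. Each of the 6 hom tumours, with 0 to 8 counts, lay below each wt tumour (32 to 75 counts) and each het tumour (32 to 61 counts). The count of 0 in hom 2 allows a level of up to 0.189 CPM. Exact two-sided permutation tests of the CPM gave p = 0.0130 for het against wt (n = 5 and 6), p = 0.00217 for hom against wt and p = 0.00217 for hom against het, with adjusted values of 0.0130, 0.00325 and 0.00325. Het 6, at 3.48 CPM, lay within the wt range of 2.93 to 4.55 CPM. The het tumour of the small intestine had 1.67 CPM. In the mm10 assembly Macrod2 occupies chromosome 2 from 140395309 to 142392966 on the + strand, 1998 kb with 14 annotated transcripts of up to 19 exons. Flrt3 lies inside it on the - strand, from 140650914 to 140671469, and its log2 fold change was 0.14 in hom against wt and -0.17 in het against wt, neither past the threshold. The labels do not say which part of Macrod2 was deleted or whether reads were counted by strand.

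**Figure D1:**
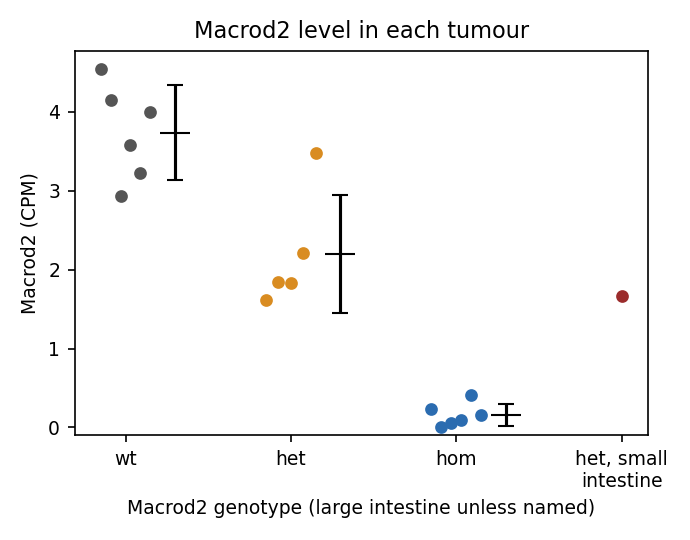
Macrod2 level in CPM (vertical axis) in each tumour, by Macrod2 genotype (horizontal axis); points are tumours, and bars give the mean and SD. The 6 hom tumours lie between 0 and 0.405 CPM, below all wt tumours (2.93 to 4.55 CPM) and het tumours (1.61 to 3.48 CPM).

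Loss of both Macrod2 copies was compared with wt to ask which transcripts depend on the gene. Macrod2 itself was lower in hom tumours, with a log2 fold change of -4.49 (SE 0.43, edgeR adjusted p = 1.17e-04). Spp1, which encodes the secreted matrix protein osteopontin, followed with 58.4 ± 12.8 CPM in wt (SD, n = 6), 39.3 ± 6.78 in het (n = 5) and 25.3 ± 9.73 in hom (n = 6). Its log2 fold change of -1.24 (SE 0.22) did not pass (edgeR adjusted p = 0.222), and over 33 alternatives its adjusted p ranged from 5.69e-04 to 0.476. The other lower genes with the smallest p were Gper1 (-1.64), a membrane oestrogen receptor, Timmdc1 (-0.63), an assembly factor of respiratory complex I, and Morc4 (-0.99). The higher ones were Map3k6 (0.78), a kinase of the MAP kinase cascade, Erc2 (1.52), Thbs3 (1.28), a thrombospondin, the palmitoyltransferase gene Zdhhc20 (0.37) and Zswim4 (0.71), and none of these 8 passed. With edgeR's quasi-likelihood test, 1 of 14271 genes passed an adjusted p of 0.05. At an unadjusted p under 0.05 there were 2277 genes, where 713.6 are expected by chance, with 1341 without wt 4, 1443 without hom 6 and 3535 without wt 1 and wt 2. DESeq2 called 22 genes, 9 higher and 13 lower, with 2424 at an unadjusted p under 0.05, and limma-voom called 2 (Macrod2 and Spp1) with 3277. Without hom 2 edgeR called 2 genes, Macrod2 and Spp1, and without hom 5 it called Macrod2 and Gper1. For genes above a mean log2 CPM of 3 the 95% interval of a fold change extended by a median of 0.331 log2 units on either side.

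Genes of oxidative phosphorylation, DNA replication, mitosis and the unfolded protein response had lower estimates as groups in hom tumours than in wt tumours, and genes of fibroblasts and extracellular matrix had higher ones. Camera called these groups with a preset correlation between genes, while the adjusted p was 0.856 for each of the 5 lists given here with an estimated correlation. All 50 tested genes of nuclear-encoded oxidative phosphorylation had a lower estimate (median log2 fold change -0.35, camera adjusted p = 1.04e-12), among them Atp5g1 (-0.64), a subunit of ATP synthase, and Uqcrb (-0.53), of complex III. All 42 genes of DNA replication and S phase did too (median -0.40, adjusted p = 5.24e-09), with Pold3, a subunit of DNA polymerase delta, at -0.69. So did 47 of 48 genes of mitosis and the spindle checkpoint (median -0.40, adjusted p = 1.56e-07), such as Aurka (-0.60) and Bub3 (-0.32), with Mad2l2 at 0.14. Of the 25 genes of the unfolded protein response 23 were lower and 2 higher (median -0.42, adjusted p = 5.92e-08). Creld2 (-1.05) and Manf (-0.91), which encode proteins of the endoplasmic reticulum, were among them, Chac1 was at 1.02, and 16 genes passed when adjusted over the list alone, against 0 over all genes. In the opposite direction, 35 of 41 genes of fibroblasts and extracellular matrix were higher (median 0.47, adjusted p = 8.13e-07), including the proteoglycan gene Dcn (0.60) and Bmp5 (1.38), while Fbln1 (-0.58) and Timp1 (-0.58) were lower. Bmp5, Dcn, Fbln1 and Timp3 passed adjusted over the list alone, against 0 members over all genes. These 5 lists kept their calls with each of the 17 tumours left out in turn, with 12 lists called in all. With the rotation test fry the adjusted p was 0.190 for the unfolded protein response and 0.639 for the others.

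Camera called 12 of 42 lists in hom against wt, 4 higher and 8 lower, with 19 past the threshold without wt 2 and 20 without wt 1 and wt 2, 11 of the 12 among them each time. The 7 lists not yet named lost the call with at least 1 tumour left out, and with an estimated correlation the adjusted p was 0.856 for each. Ribosomal proteins were lower (57 of 58 members, median -0.23, adjusted p = 7.63e-05, 0.0781 without wt 4). Homologous recombination and Fanconi anaemia genes were lower too (32 of 33, median -0.24, adjusted p = 9.06e-04, 0.0523 without hom 3), such as Nbn (-0.33) and Rad51c (-0.97). Replication-dependent histones were lower (20 of 21, median -0.70, adjusted p = 4.81e-04, 0.0721 without wt 3), and in wt 3 their score was 1.58 log2 units above the mean of the 17 tumours. The same library held 27.0% Rn45s, and Rpph1 and Rmrp, other RNAs without a polyA tail, at 287 and 260 CPM, against medians of 1.69 and 1.65 CPM over the 15 large intestinal tumours other than wt 1 and wt 2. Several histone genes are near-identical copies, so the split of reads among them is uncertain. Mast cell and eosinophil genes were lower (12 of 13, median -3.31, adjusted p = 0.00393, 0.0722 without wt 2). Of these 9 passed adjusted over the list alone, against 0 over all genes, among them the protease gene Mcpt2 (-3.88) and the IgE receptor gene Ms4a2 (-3.32). In wt 2 Mcpt2 stood at 2690 CPM, in wt 1 at 56.1 CPM and in the 15 other large intestinal tumours at 8.63 to 574 CPM. Colonic surface enterocyte genes were higher (20 of 26, median 0.20, adjusted p = 7.92e-04, 0.0575 without wt 4), with Guca2a (1.13), which encodes guanylin, and the aquaporin gene Aqp4 (1.30). Endothelial genes were higher (19 of 26, median 0.29, adjusted p = 0.0248), such as Ptprb (0.98), but leaving out wt 3, wt 4, wt 5, wt 6, hom 1, hom 4 or hom 6 gave adjusted p values of 0.0677 to 0.413, the highest without hom 6. Genes of the small intestinal epithelium tested as higher (adjusted p = 0.00267) although their median was -0.31, their mean -0.60 and 16 of 24 were lower. These fold changes are edgeR estimates, while camera compares log2 CPM. In log2 CPM the mean score of the list was 0.529 in hom (SD 0.945) and -0.541 in wt (SD 2.385). Among its genes Fabp6 was at 2.18 and Lct at -4.73, and without wt 4, wt 5 or wt 6 the adjusted p was 0.0558 to 0.191. For Lct, hom versus wt, the estimate turned to 3.82 without wt 1 and wt 2. With fry the adjusted p was 0.639 for each of these 7 lists.

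**Figure D2:**
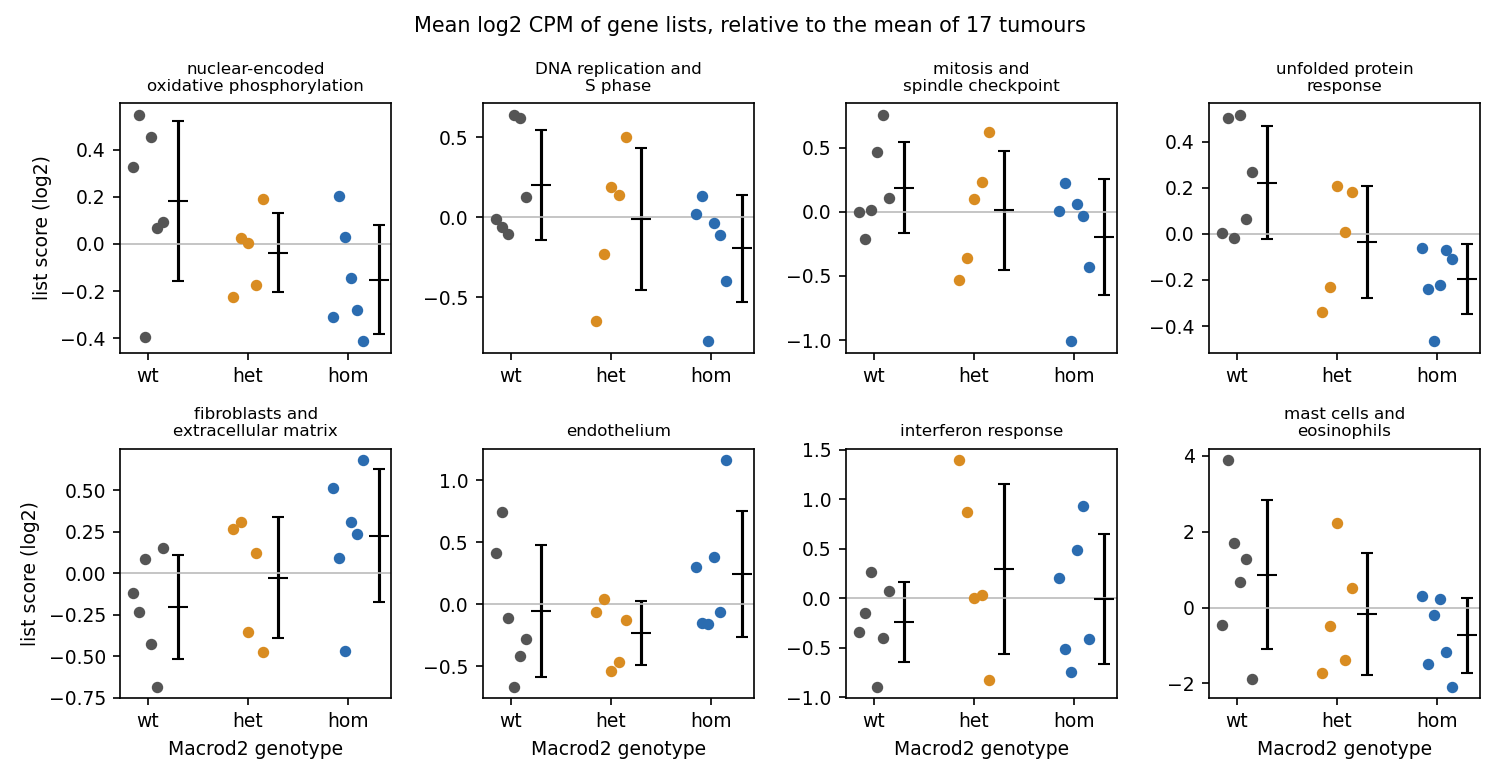
Scores of 8 gene lists (vertical axes, mean log2 CPM of the members relative to the mean of the 17 tumours) in each large intestinal tumour, by Macrod2 genotype (horizontal axes); points are tumours, and bars give the mean and SD. Single tumours stand apart in several lists, such as wt 2 at 3.89 for mast cells and eosinophils and hom 6 at 1.16 for endothelium.

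Loss of 1 Macrod2 copy addressed the haploinsufficiency that the series title names. Het tumours had higher estimates for interferon response genes and lower estimates for respiratory chain and unfolded protein response genes than wt tumours, with an adjusted p of 0.911 for each of these 3 lists with an estimated correlation. Of 48 interferon response genes, 46 had a higher estimate (median log2 fold change 0.57, camera adjusted p = 9.94e-11), including the chemokine gene Cxcl9 (3.32) and the antiviral gene Rsad2 (1.61). Their score was spread widely within het, from -0.822 in het 6 to 1.395 in het 1. All 50 genes of nuclear-encoded oxidative phosphorylation were lower (median -0.25, adjusted p = 1.54e-12, 0.0853 without wt 1 and wt 2 for the list nuclear-encoded oxidative phosphorylation, het versus wt), with Cycs, which encodes cytochrome c, at -0.44 and Uqcrb at -0.40. So were 24 of 25 unfolded protein response genes (median -0.28, adjusted p = 2.89e-07), such as Dnajb11 (-0.34) and Manf (-0.51).

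No gene passed in het against wt with edgeR (0 of 14271, 407 at an unadjusted p under 0.05, smallest adjusted p 0.999), DESeq2 (0, with 498) or limma-voom (0, with 685). The 407 genes lay below the 713.6 expected by chance, with 204 without het 1, 249 without het 2, 819 without wt 3, 970 without het 6 and 1055 without wt 1 and wt 2. Macrod2 itself had a log2 fold change of -0.80 (SE 0.37) and an edgeR adjusted p of 0.999 over all genes. The smallest p values belonged to Trpm6 (0.89), an epithelial magnesium channel, Pcdhb11 (1.48), Me3 (1.33), Ppfia3 (1.03) and Prx (0.67) among higher genes, and to Ap3s1 (-0.35), Gstm3 (-2.46), a glutathione transferase, Bet1 (-0.37), Ccdc114 (-0.997) and Tram1 (-0.35) among lower genes. Gstm3 stood at 76.8 CPM in wt 1 and 34.1 CPM in wt 2, and at 3.08 to 8.03 CPM in the 15 other large intestinal tumours.

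Camera called 13 of 42 lists in het against wt, 5 higher and 8 lower, of which interferon response, oxidative phosphorylation and the unfolded protein response kept their calls with each tumour left out. With an estimated correlation the adjusted p was 0.911 for each of the 13 lists, and with fry 0.961. DNA replication and S phase (40 of 42 lower, median -0.18, adjusted p = 2.89e-06) was at 0.214 without het 1. Mitosis and the spindle checkpoint (47 of 48 lower, median -0.16, adjusted p = 9.61e-04) was at 0.164 to 0.481 without wt 5, het 1 or het 2. Ribosomal proteins (55 of 58 lower, median -0.18, adjusted p = 1.17e-04) were at 0.650 without wt 4. Homologous recombination and Fanconi anaemia (24 of 33 lower, median -0.10, adjusted p = 0.0332) was at 0.0560 to 0.808 without wt 3, wt 4, wt 5, het 1 or het 2. Replication-dependent histones (19 of 21 lower, median -0.74, adjusted p = 1.82e-04) were at 0.195 without wt 3, the tumour with the highest histone score and 27.0% Rn45s. Mast cells and eosinophils (12 of 13 lower, median -1.60, adjusted p = 0.00528) were at 0.324 without wt 2. Colonic surface enterocytes tested as higher (16 of 26, median 0.07, adjusted p = 0.00119), with 0.0787 to 0.464 without wt 4 or wt 5. Fibroblasts and extracellular matrix (32 of 41 higher, median 0.18, adjusted p = 0.00715) were at 0.0794 to 0.590 without wt 4, wt 5, het 1, het 2 or het 5. Macrophages and monocytes (18 of 26 higher, median 0.13, adjusted p = 0.0491) lost the call with 12 of the 17 tumours left out, up to 0.973 without wt 5. The small intestinal epithelium tested as higher (adjusted p = 0.0332), although 17 of its 24 genes were lower, its median was -0.86 and its mean -1.11, and it lost the call with 11 tumours left out, up to 0.800 without wt 4. These fold changes are edgeR estimates, while in the log2 CPM that camera compares its mean score was 0.0145 in het (SD 0.913) and -0.541 in wt (SD 2.385). No list member passed adjusted over the list alone.

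Hom tumours were next set against het tumours, to separate the loss of the second copy from the loss of the first. Endothelial, matrix, hypoxia and interferon response genes were called as groups by camera, with an adjusted p of 0.786 for each of these 4 lists with an estimated correlation. Of 26 endothelial genes, 25 had a higher estimate in hom tumours (median log2 fold change 0.57, camera adjusted p = 5.22e-09), with Ptprb, an endothelial tyrosine phosphatase, at 1.22 and Vwf, von Willebrand factor, at 0.83. The endothelial score of hom 6 was 1.16, and the other hom tumours ranged up to 0.38. Genes of fibroblasts and extracellular matrix (35 of 41 higher, median 0.27, adjusted p = 7.42e-06), such as Dcn (0.42) and Col6a2 (0.72), and of hypoxia and glycolysis (23 of 29 higher, median 0.16, adjusted p = 5.63e-05), such as Kdm3a (0.30) and Ndrg1 (0.54), were also higher. Interferon response genes were lower (47 of 48, median -0.38, adjusted p = 7.42e-06, 0.322 without het 1), with Bst2 at -0.65 and Ifit3 at -1.21.

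Macrod2 (-3.69, SE 0.44, edgeR adjusted p = 0.00233) was the 1 gene of 14271 that passed in hom against het; 286 genes had an unadjusted p under 0.05, below the 713.6 expected by chance. That number was 145 without hom 6, 156 without het 3, 167 without het 5, 181 without het 6, 477 without hom 2 and 606 without het 1. DESeq2 and limma-voom each called 1 gene, with 349 and 441 at an unadjusted p under 0.05. For the Macrod2 level, hom versus het, the estimate was -3.68 and the adjusted p 0.0917 when edgeR was fitted to the het and hom tumours alone, and over 31 alternatives the adjusted p ranged from 2.32e-14 to 0.0917. Genes with the smallest p among the rest were Zfp943 (0.33), Ap3s1 (0.34), Zdhhc20 (0.31), the ubiquitin-conjugating enzyme gene Ube2d3 (0.32) and Mir703 (0.72) on the higher side, and Nr4a1 (-0.65), an immediate early nuclear receptor, Pex6 (-0.34), Gata5 (-0.32) and AI467606 (-0.60) on the lower side.

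Camera called 14 of 42 lists in hom against het, 7 higher and 7 lower, with 8 past the threshold without het 6 and 9 without hom 6. With an estimated correlation the adjusted p was 0.764 for genes that differ between C57BL/6 substrains and 0.786 for the 13 other lists, and with fry it was 0.887 for all. Endothelium, fibroblasts and extracellular matrix, hypoxia and glycolysis, and the unfolded protein response (20 of 25 lower, median -0.15, adjusted p = 0.00132) kept their calls with each tumour left out. Mitosis and the spindle checkpoint (47 of 48 lower, median -0.21, adjusted p = 1.91e-05) was at 0.349 to 0.356 without het 6 or hom 3. DNA replication and S phase (40 of 42 lower, median -0.22, adjusted p = 5.66e-05) was at 0.132 to 0.356 without het 6 or hom 3. Oxidative phosphorylation (48 of 50 lower, median -0.10, adjusted p = 4.15e-04) was at 0.0882 to 0.150 without het 6 or hom 6. Base excision and single-strand break repair (17 of 22 lower, median -0.11, adjusted p = 0.0147) was at 0.0535 to 0.422 without het 6, hom 1, hom 3 or hom 6. Homologous recombination and Fanconi anaemia (28 of 33 lower, median -0.13, adjusted p = 0.0147) was at 0.0700 to 0.792 without het 5, het 6 or hom 3. Red blood cells (6 of 6 higher, median 0.56, adjusted p = 0.0291) were at 0.0582 to 0.198 without het 2, het 3, het 6, hom 1, hom 2 or hom 3. Fatty acid oxidation and PPAR targets (20 of 28 higher, median 0.086, adjusted p = 0.0316) were at 0.0638 to 0.273 without het 2, het 5, het 6, hom 3 or hom 6. The small intestinal epithelium (16 of 24 higher, median 0.26, adjusted p = 0.0345) lost the call with 8 tumours left out, up to 0.273 without het 6. Genes that differ between C57BL/6 substrains (6 of 7 higher, median 0.27, adjusted p = 0.0316), with Mmrn1 at 1.60 and Nnt at 0.25, were at 0.0546 to 0.148 without het 1, het 2, hom 1, hom 2 or hom 6. In hom 6 their score was 0.658 and Mmrn1 stood at 15.9 CPM, against 0.00166 to 0.239 and 1.48 to 3.33 CPM in the other hom tumours.

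Het and hom tumours were also compared with wt as carriers of a lost copy, at equal weight. Camera called the 5 lists given here, while the adjusted p was 0.899 for each with an estimated correlation. Oxidative phosphorylation (50 of 50 lower, median log2 fold change -0.30, camera adjusted p = 4.25e-14), DNA replication and S phase (42 of 42, median -0.29, adjusted p = 1.21e-08), mitosis and the spindle checkpoint (47 of 48, median -0.28, adjusted p = 1.92e-06) and the unfolded protein response (24 of 25, median -0.37, adjusted p = 1.49e-08) were lower in carriers than in wt tumours. Fibroblast and matrix genes were higher (35 of 41, median 0.35, adjusted p = 1.74e-05). The unfolded protein response had 13 members past the threshold adjusted over the list alone, including Manf (-0.71) and Dnajb11 (-0.44). Spp1 was lower by estimate (-0.92, SE 0.19, edgeR adjusted p = 0.432), with Gstm3 (-2.38), Gper1 (-1.25) and Bet1 (-0.38), and Pcdhb11 (1.58), Trpm6 (0.86), Erc2 (1.19), Gpr161 (1.03) and Thbs3 (1.02) were higher by estimate, none past the threshold.

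Macrod2 was the 1 gene that passed in carriers against wt (-2.64, SE 0.32, edgeR adjusted p = 0.00277), with 1594 genes at an unadjusted p under 0.05, where 713.6 are expected by chance, and 872 without wt 4, 958 without het 1 and 2842 without wt 1 and wt 2. DESeq2 called 3 (Gstm3, Macrod2 and Spp1) with 1723, and limma-voom 1 with 2431. Gstm3 was at 76.8 and 34.1 CPM in wt 1 and wt 2, and at 40.7 CPM in the small intestinal tumour. In the 15 other large intestinal tumours it was at 3.08 to 8.03 CPM. Other splits of the same tumours into groups of the same sizes also exceeded 1594 genes at an unadjusted p under 0.05. Such splits gave 2461 and 2019, for instance, so chance cannot be excluded for the 1594 genes. For the Macrod2 level, carriers versus wt, the adjusted p was 0.0553 (log2 fold change -2.50) without wt 1 and wt 2 and 0.424 (-1.78) with het and hom merged into a single group, and over 31 alternatives it ranged from 2.81e-17 to 0.424. Camera called 12 of 42 lists, 4 higher and 8 lower, with 19 past the threshold without wt 2 and 21 without wt 1 and wt 2. With an estimated correlation the adjusted p was 0.899 for each list, and with fry the smallest was 0.336, for the unfolded protein response. Ribosomal proteins (56 of 58 lower, median -0.20, adjusted p = 2.41e-05) were at 0.206 without wt 4. Histones (20 of 21 lower, median -0.72, adjusted p = 1.09e-04) were at 0.0948 without wt 3, which held 27.0% Rn45s, and Hist1h4c, Hist1h4d and Hist1h4h passed adjusted over the list alone, against 0 members over all genes. Homologous recombination and Fanconi anaemia (29 of 33 lower, median -0.15, adjusted p = 0.00208) was at 0.0773 to 0.187 without wt 4 or wt 5. Mast cells and eosinophils (12 of 13 lower, median -2.47, adjusted p = 0.00208), with 9 members passing adjusted over the list alone, were at 0.122 without wt 2. Colonic surface enterocytes (18 of 26 higher, median 0.19, adjusted p = 4.02e-04) were at 0.108 without wt 4. Interferon response (44 of 48 higher, median 0.37, adjusted p = 5.27e-04) was at 0.0600 to 0.0605 without wt 4 or het 1. The small intestinal epithelium tested as higher (adjusted p = 0.00430), although its median was -0.64 and its mean -0.85, and was at 0.0571 to 0.610 without wt 4, wt 5, wt 6 or hom 6. These fold changes are edgeR estimates, while camera compares log2 CPM, with mean scores of 0.0145 in het, 0.529 in hom and -0.541 in wt (SD 2.385). In this list Adh6a (-3.87), Fabp1 (-4.03) and Lct passed adjusted over the list alone. For Adh6a, carriers versus wt, and Fabp1, carriers versus wt, the estimates turned to 2.63 and 2.75 without wt 1 and wt 2. Lct was at 924 and 1660 CPM in wt 1 and wt 2, at 0.338 to 2.40 CPM in the other wt tumours and at 0.303 to 45.6 CPM in carriers.

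The het and hom comparisons share their wt tumours. Across the 14271 genes the log2 fold changes of het against wt and hom against wt correlated at r = 0.786. In 20 simulations with no difference between genotypes, wt counts included, the mean was 0.484 (0.465 to 0.509). Each gene was simulated by itself, without the correlation between genes of real tumours, so this range is no bound for chance. With the wt tumours split into 3 for each comparison, the mean over 20 splits was 0.182, with a range of -0.326 to 0.514. The covariance was 0.128, against 0.0498 simulated and 0.0318 with split wt tumours (-0.12 to 0.0961). At an unadjusted p under 0.05, 102 higher genes were shared by the 169 of het and 763 of hom, where independent lists share 9.04, and 157 lower genes by 238 and 1514, where independent lists share 25.2. No gene was shared at the adjusted threshold, where edgeR called 0 and 1. Genes are not independent replicates. With split wt tumours the covariance was below the observed 0.128 in all 20 splits, so part of the agreement in fold changes came from sharing wt tumours. Part of the excess of shared genes may come from them too, and how much was not tested.

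Other genes of ADP-ribosylation, Wnt signalling and the cell cycle on the fixed list did not pass over all genes in any comparison. In hom against wt the log2 fold changes were -0.33 (SE 0.14) for Parp1, which adds ADP-ribose to proteins at DNA breaks, -0.30 for Parp2, -0.09 for Parg, which degrades poly(ADP-ribose), and 0.37 for the paralog Macrod1. Among genes of Wnt signalling and proliferation, Apc was at 0.30, Axin2 at 0.44, Myc at -0.19, Ccnd1 at -0.40 (SE 0.17), Lgr5 at -0.0094, Mki67 at -0.50 (SE 0.25) and Top2a at -0.40. Trp53 was at -0.30 and its target Cdkn1a at 0.29, and Cdkn2a, an inhibitor of the cell cycle, at -1.004 (SE 0.63). As groups, the ADP-ribosylation enzymes (27 genes, camera adjusted p = 0.880), p53 targets (30 genes, 0.702), Wnt targets (25 genes, 0.161), intestinal stem cell genes (19 genes, 0.701), non-homologous end joining (11 genes, 0.265), cytosolic DNA sensing and NF-kB cytokines (30 genes, 0.940) and genes near Macrod2 (21 genes, 0.701) did not pass in hom against wt. Adjusted over the list alone, 2 ADP-ribosylation genes passed in hom against wt, Art3 (-1.57) and Nudt5 (-0.69), and 1 in carriers against wt, Art3, against 0 over all genes. So did 4 immediate early and heat shock genes in hom against wt, Fosl1 (-0.89), Hsp90aa1 (-0.93), Hspa8 (-0.72) and Hsph1 (-1.98), and Nr4a1 in hom against het, against 0 over all genes. Spp1 passed in hom and in carriers against wt when adjusted over the list alone for macrophages and monocytes and for regeneration and fetal-like genes. In all, camera called 23 of 42 lists in no comparison, and the smallest adjusted p among them was 0.0508, for Paneth cells in het against wt.

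Tumours wt 1 and wt 2, labelled as large intestinal, carried some transcripts of the proximal small intestine near the level of the tumour labelled as small intestinal. These genes were chosen after their values were seen, and no test was run. Gata4, a transcription factor of the proximal small intestine, stood at 171 and 179 CPM in wt 1 and wt 2 and at 166 CPM in the small intestinal het tumour, against 0.282 to 47.3 CPM in the 15 other tumours. Lct, which encodes lactase, was at 924 and 1660 CPM, against 821 CPM in the small intestinal tumour and 0.303 to 45.6 CPM in the others. Fabp1 (2530 and 1740 CPM, small intestinal tumour 1680, others 1.90 to 363) and Adh6a (226 and 205 CPM, small intestinal tumour 219, others 0.563 to 21.8) were also above the others. Fabp6, the ileal bile acid binding protein, ran the other way, with 2.06 and 1.73 CPM in wt 1 and wt 2, 2.30 CPM in the small intestinal tumour and 11.2 to 1660 CPM (median 654) in the 15 others. Car1, a carbonic anhydrase of the colon, reached at most 6.59 CPM in the 17 tumours labelled large intestinal, with 0.0606 in wt 1 and 1.59 in wt 2. Hoxb13, a homeobox gene of the distal colon, reached at most 1.04 CPM, and this highest value was in wt 2. It was at 0 in wt 1 and the small intestinal tumour and at most 0.275 CPM in the 15 others, all low levels. Of 15 posterior Hox genes, 3 passed the expression filter, too few for a test of that list.

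**Figure D3:**
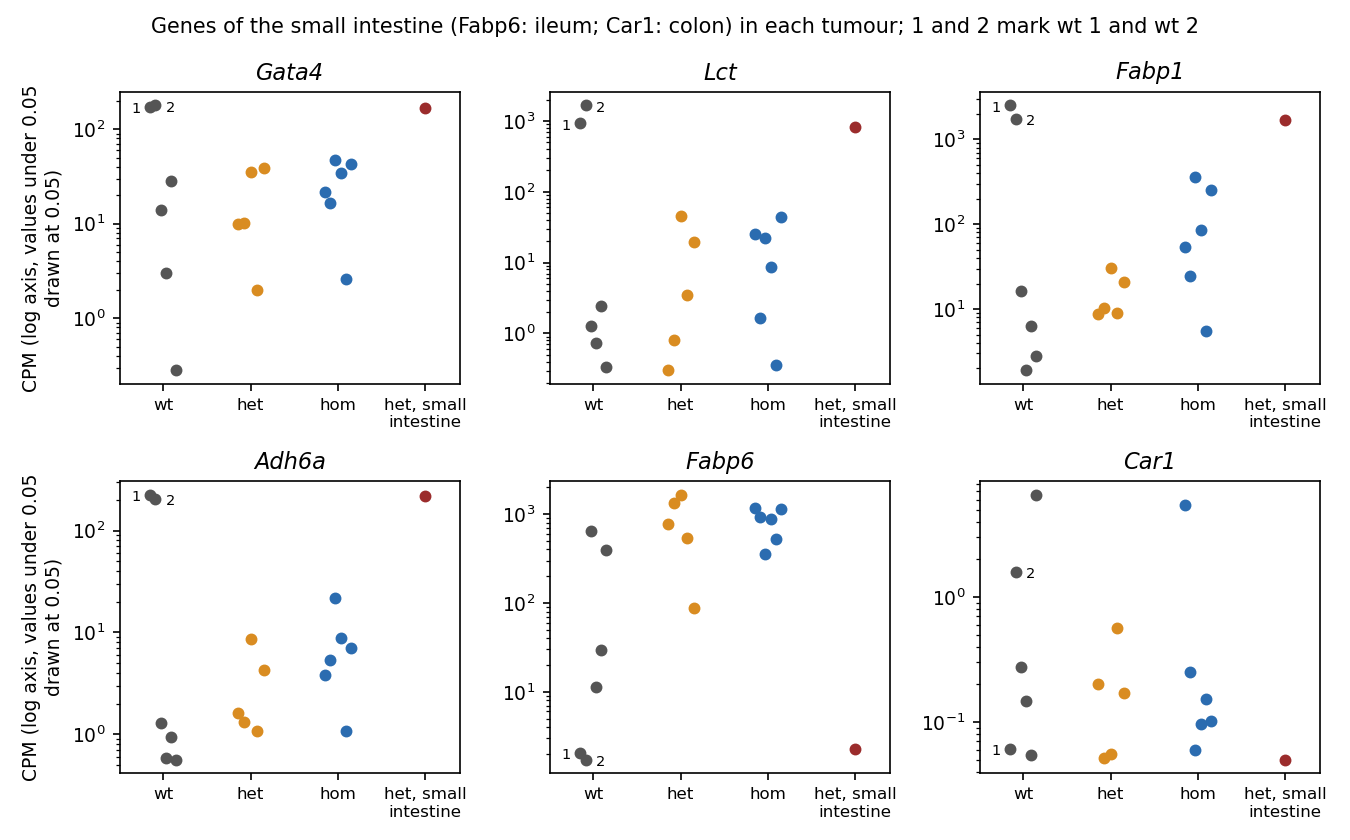
Levels in CPM (vertical axes, log scale) of 6 genes with regional expression along the intestine, in each tumour by Macrod2 genotype (horizontal axes); points are tumours, wt 1 and wt 2 are numbered, and values under 0.05 CPM are drawn at 0.05. Wt 1 and wt 2 lie near the small intestinal tumour for Gata4, Lct, Fabp1, Adh6a and Fabp6 and away from the other large intestinal tumours.

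Chromosome-wide expression was compared because a gained or lost chromosome shifts the transcripts of its genes together. The imbalance of a tumour, the SD over 19 autosomes of the median log2 difference of their genes from the baseline, was 0.0247 ± 0.0155 in wt (SD, n = 6), 0.0197 ± 0.0106 in het (SD, n = 5) and 0.0301 ± 0.0129 in hom tumours (SD, n = 6). Exact two-sided permutation tests gave p = 0.634 for het against wt, 0.517 for hom against wt and 0.204 for hom against het, with adjusted values of 0.634, 0.634 and 0.610 (n = 5 or 6). The difference of hom from wt was 0.0055, and for the chromosome-wide expression imbalance, hom versus wt, it was -0.0037 with the mean over genes in place of the median and -0.0021 with the GC trend of each library removed. It was 0.0014 without hom 1, 0.0035 without hom 2, 0.0102 without hom 4 and 0.0119 without wt 4. The difference of het from wt was -0.0049, and it was 0.0027 without wt 4. No chromosome differed between genotypes in 57 exact permutation tests (0 calls, smallest adjusted p 0.991). Single shifts ran from -0.138 for chromosome 18 in wt 4 to 0.115 for chromosome 15 in het 6, where a gain of 1 copy in all cells corresponds to 0.585. Every autosome of het 6 lay above the baseline, the lowest at 0.00638 for chromosome 18, so the 0.115 is not particular to chromosome 15. With the GC trend removed, chromosome 15 in het 6 was at 0.0578. Chromosome 18 carries Apc; in the wt tumours other than wt 4 it ranged from -0.0445 to 0.0501, in het from -0.0594 to 0.0333 and in hom from -0.0482 to 0.0686.

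**Figure D4:**
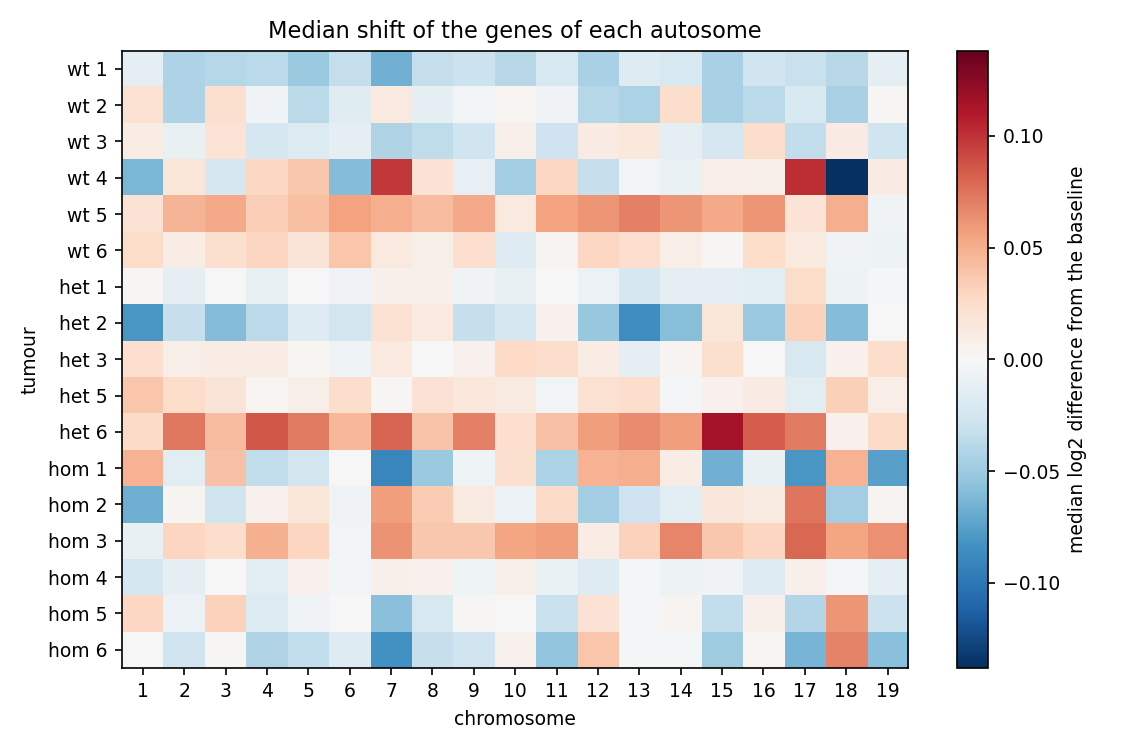
Median log2 difference of the genes of each autosome (horizontal axis) from the baseline, as colour, in each large intestinal tumour (vertical axis). The lowest value is -0.138, for chromosome 18 in wt 4, and the highest 0.115, for chromosome 15 in het 6.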

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

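The removal of the GC trend, the bootstrap intervals and the choice of the pattern to weigh were made only after the data were seen.

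Among groups of 5 or 6 tumours of 1 genotype, a value was singled out when its gap to the nearest other tumour took an unusually large share of the range of the group. This gave 24 values in 408 groups, where chance alone gives 20.4. In wt 2, Angptl4 was at 50.7 CPM, against 8.51 to 15.6 in the other wt tumours. In wt 3, Cxcl9 was at 7.69 CPM (others 0.73 to 1.80), Hist1h4c at 6.41 (0.484 to 0.849), Hist1h4d at 10.9 (0.563 to 1.17) and Hist1h4h at 8.24 (1.09 to 1.97), and Rn45s took 27.0% of the counts (0.186% to 0.725%). In wt 4, Gpr161 was at 0.365 CPM (0.898 to 1.19). In het 1, Bst2 was at 21.9 CPM (13.2 to 15.1) and Fech at 65.9 (48.9 to 53.2). In het 6, Myc was at 142 CPM (74.9 to 91.6) and Tmigd1 at 16.9 (at least 261), and the macrophage and monocyte score was -0.583 (0.10 to 0.352). In hom 3, Axin2 was at 442 CPM (304 to 340), Creld2 at 37.9 (56.1 to 63.7), Fancg at 4.73 (7.90 to 10.3), Pdia6 at 187 (308 to 395), Prx at 1.60 (2.52 to 3.11), Top2a at 143 (276 to 393) and Zswim4 at 56.8 (31.8 to 38.8), and the homologous recombination and Fanconi anaemia score was -0.772 (-0.166 to 0.0808). In hom 5, Pex6 was at 31.8 CPM (42.9 to 46.6). In hom 6, Mmrn1 was at 15.9 CPM (1.48 to 3.33), and the score of genes that differ between C57BL/6 substrains was 0.658 (0.00166 to 0.239).

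The chromosome-wide imbalance of wt 4 was 0.0551, against 0.0134 to 0.0247 in the other wt tumours, with chromosome 18 at -0.138 as its largest shift. Copy number changes in part of the cells would move the first and second parts of a chromosome, divided at its middle gene, together, and after the GC trend was removed the shifts of these parts over tumours and chromosomes correlated at -0.0394 over 323 pairs, against 0.268 before. The bootstrap interval was -0.123 to 0.0177 over tumours but -0.329 to 0.233 over tumours and chromosomes, and parts of different chromosomes correlated at -0.264 to 0.337, so copy number stays open, as does a loss in wt 4, where the parts of chromosome 18 were at -0.0423 and -0.173. GC content may account for part of the shifts, since 72.2% of the median imbalance was left once its trend was removed, a share between the bounds set for a full cause and for none, while wt 4 itself was left with 0.0446 of 0.0551 and chromosome 18 at -0.117. Macrod2 loss, the biological explanation that the design offers, cannot be the source in wt 4, which is labelled wt. Its Macrod2 level of 3.58 CPM lay above every large intestinal het tumour (1.61 to 3.48 CPM) and hom tumour (0 to 0.405 CPM). For the shifts in other tumours Macrod2 loss stays open (exact permutation p = 0.517 for imbalance in hom against wt, n = 6).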

How the results depend on the processing

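The fits without Rn45s, Lars2, Rpph1 and Rmrp, with the Gata4 covariate, without wt 1 and wt 2, with 2 surrogate variables and with GC content and length trends removed were chosen after the data were seen. The 208 gene estimates other than those of Macrod2, given below, had 6823 values under the alternatives, of which 6681 kept their direction and side of the threshold, 15 passed it newly and 127 changed sign. Of the 1275 values of the 51 list calls, 1041 kept the call, 233 lost it and 1 changed sign. The call was lost in 102 values with an estimated correlation or fry, which is every list under both, and in 131 other values of 35 lists. The depth, 13529204 to 20857918 counts, limits genes as low as Macrod2, at 3.74 CPM in wt. Of the 16 pairs of tumours with the same mouse number, 4 correlated above 0.1 (-0.452 to 0.325), and 1 of 17 tumours correlated best with its own number, so the numbers were not taken to pair the tumours.

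With genes changed, hom versus wt, at 1 in the report, the block gave 2 (Macrod2 and Spp1), DESeq2 22, limma-voom 2 (Macrod2 and Spp1), and leaving out each tumour 1 to 2, with Spp1 added without hom 2 and Gper1 without hom 5. In hom against het, at 1, the count was 0 with the block and the compared genotypes alone. In carriers against wt, at 1, it was 0 with the block, het and hom merged, and without wt 1 and wt 2, 3 with DESeq2 and 2 with 2 surrogate variables (Macrod2 and Tmem135). For the Macrod2 level, hom versus het, the block gave -3.71 (adjusted p = 0.0785) and the compared genotypes alone -3.68 (0.0917). For the Macrod2 level, carriers versus wt, the block gave -2.73 (0.0660), the merged group -1.78 (0.424) and the fit without wt 1 and wt 2 -2.50 (0.0553). The block spends degrees of freedom, and fits of fewer tumours test with less. Both fits of RPKM gave 0 in these 3 comparisons, since Macrod2, at 0.902 RPKM or less, was below their filter and was not tested, so they say nothing about its call; the cause of the other changes was not tested. At an unadjusted p under 0.05, het against wt had 407 genes, with 165 with the block, 233 with the compared genotypes alone, 258 and 260 with RPKM, 259 with all 18 tumours and 1061 with 2 surrogate variables. Hom against het had 286, with 439 with the compared genotypes alone, 563 with all 18 tumours and 596 with 2 surrogate variables, and carriers 1594, with 913 with the block and 2476 with 2 surrogate variables. The DESeq2 counts past the adjusted threshold in the other comparisons were 0 for het against wt and 1 for hom against het.

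Lists past the camera threshold numbered 0 in all 4 comparisons with an estimated correlation and with fry. In hom against wt they numbered 12, with 8 to 19 when a tumour was left out (19 without wt 2, 11 of them shared) and 20 without wt 1 and wt 2 (11 shared). In hom against het they numbered 14, with 8 to 18 when a tumour was left out (8 without het 6, 9 without hom 6) and 9 with all 18 tumours. In carriers they numbered 12, with 9 to 19 when a tumour was left out (19 without wt 2) and 21 without wt 1 and wt 2 (11 shared). The difference in chromosome-wide expression imbalance, het versus wt, was -0.0049, with -0.0087 to 0.0027 when a tumour was left out, positive without wt 4. The chromosome-wide expression imbalance, hom versus wt, changed from 0.0055 to -0.0037 with the mean over genes and to -0.0021 with the GC trend removed, with 0.0014 to 0.0119 when a tumour was left out. No imbalance difference passed the threshold under any alternative, and the cause was not tested.

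No gene or list estimate passed the threshold after its sign changed (128 values of 28 results, 102 of them of genes with a reported log2 fold change within 0.3 of 0), and the cause was not tested, apart from the fit without wt 1 and wt 2, which removes the 2 tumours with the highest levels of Adh6a, Lct and Fabp1. The log2 fold changes of changed sign were as follows. With the mouse number as a block, these were Ada, hom versus het 0.18, Apc, het versus wt -0.0048, Cdkn2a, het versus wt 0.098, Lgr5, carriers versus wt 0.040, Lgr5, het versus wt 0.018, Lgr5, hom versus wt 0.062, Mep1a, hom versus het 0.13, Parg, hom versus het 0.014, Trp53, het versus wt 0.032. With limma-voom, these were Adh6a, carriers versus wt 0.27, Adh6a, hom versus wt 0.77, Alpi, carriers versus wt 0.72, Alpi, het versus wt 0.65, Cdkn2a, het versus wt 0.16, Fabp1, carriers versus wt 0.52, Lct, hom versus wt 0.51, Lgr5, hom versus het -0.024, Myc, hom versus het 0.040. Without wt 1 and wt 2, these were Adh6a, carriers versus wt 2.63, Adh6a, het versus wt 2.02, Adh6a, hom versus wt 3.25, Alpi, carriers versus wt 1.46, Alpi, het versus wt 1.33, Fabp1, carriers versus wt 2.75, Fabp1, het versus wt 1.24, Lct, hom versus wt 3.82. With a pseudocount of 0.1 on RPKM, these were Adh6a, hom versus wt 0.011, Alpi, carriers versus wt 0.50, Alpi, het versus wt 0.33, Cdkn2a, het versus wt 0.14, Lgr5, carriers versus wt 0.13, Lgr5, het versus wt 0.11, Lgr5, hom versus wt 0.14, Myc, hom versus het 0.0058. With a pseudocount of 1, these were Alpi, carriers versus wt 0.44, Alpi, het versus wt 0.26, Cdkn2a, het versus wt 0.058, Lgr5, carriers versus wt 0.12, Lgr5, het versus wt 0.11, Lgr5, hom versus wt 0.13, Myc, hom versus het 0.0055. With 2 surrogate variables, these were Apc, het versus wt -0.044, Cdkn2a, carriers versus wt 0.075, Cdkn2a, het versus wt 0.41, Lgr5, carriers versus wt 0.15, Lgr5, het versus wt 0.049, Lgr5, hom versus wt 0.25, Macrod1, hom versus het -0.069, Parg, hom versus het 0.0045, Parp2, hom versus het 0.0077, Trp53, het versus wt 0.026. With GC content and length trends removed, these were Cdkn2a, het versus wt 0.14, Lgr5, hom versus het -0.029, Myc, hom versus het 0.029. With all 18 tumours, these were Fabp1, hom versus het -1.16, Lgr5, hom versus wt 0.0016, Myc, hom versus het 0.0033. With RLE factors, these were Lgr5, carriers versus wt 0.0025, Lgr5, hom versus wt 0.013. Without a filter, these were Lgr5, carriers versus wt 0.0032, Lgr5, hom versus wt 0.0098. With DESeq2, these were Lgr5, carriers versus wt 0.0026, Lgr5, hom versus wt 0.013. With the Gata4 covariate, these were Lgr5, carriers versus wt 0.074, Lgr5, het versus wt 0.0022, Lgr5, hom versus wt 0.15. With the compared genotypes alone, these were Lgr5, het versus wt 0.0071, Lgr5, hom versus wt 0.031. Without Rn45s, Lars2, Rpph1 and Rmrp, these were Lgr5, hom versus wt 0.0073. With each tumour left out, the estimate ran from -0.65 to 0.62 for Ada, hom versus het, -0.013 to 0.19 for Apc, het versus wt, -0.21 to 0.018 for Ccnd1, het versus wt, -0.76 to 0.012 for Cdkn2a, carriers versus wt. It ran from -0.39 to 0.48 for Cdkn2a, het versus wt, -0.17 to 0.26 for Lgr5, carriers versus wt, -0.17 to 0.25 for Lgr5, het versus wt, -0.073 to 0.14 for Lgr5, hom versus het. It ran from -0.16 to 0.26 for Lgr5, hom versus wt, -0.043 to 0.31 for Macrod1, hom versus het, -0.31 to 0.037 for Mki67, hom versus het, -0.083 to 0.17 for Myc, hom versus het. It ran from -0.093 to 0.025 for Parg, het versus wt, -0.092 to 0.049 for Parg, hom versus het, -0.13 to 0.0076 for Parg, hom versus wt, -0.15 to 0.054 for Parp2, hom versus het. It ran from -0.14 to 0.075 for Trp53, het versus wt. The adjusted p of the list small intestinal epithelium, het versus wt, ran from 1.1e-04 to 0.800, the latter without wt 4 and with the opposite sign.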

Other observations

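The tests of tumour site, of carry-over and of the Gata4 covariate, the removal of GC content and length trends and the fits without wt 1 and wt 2 were chosen only after the result was seen.

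Transcripts of the ileum were present in tumours labelled large intestinal. Fabp6 and the ileal bile acid transporter gene Slc10a2, both of the distal small intestine, were measured in most tumours labelled large intestinal, with medians of 654 and 47.3 CPM over 15 tumours, while Car1 had a median of 0.152 CPM there. Onecut2 was lower in wt 1 (91.8 CPM), wt 2 (126 CPM) and the small intestinal tumour (126 CPM) than in the other tumours (164 to 288 CPM), and Adora2b was higher (8.24, 8.91 and 9.83 CPM against 0.304 to 1.69). These values were read gene by gene, with no test between sites, since 1 tumour carries the small intestinal label.

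Mcpt1, a mucosal mast cell protease gene, was at 4610 CPM in wt 2, 37.3 CPM in wt 1, 695 CPM in the small intestinal tumour and 8.22 to 868 CPM in the others. Reg3b, an antimicrobial lectin gene, ranged from 216 CPM in wt 2 to 6560 CPM in hom 5. In wt 3, the library with 27.0% Rn45s, Rpph1 and Rmrp, structural RNAs, were at 287 and 260 CPM and Lars2, which encodes a mitochondrial leucyl-tRNA synthetase, at 19300 CPM, against medians of 1.69, 1.65 and 761 CPM over the 15 large intestinal tumours other than wt 1 and wt 2. Whether the Lars2 reads of wt 3 come from its mRNA was not tested.

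Some small intestinal genes, such as Gata4 and Lct, were higher in the tumours wt 1 and wt 2 than in the 15 other large intestinal tumours. Sis (1620 and 781 CPM, others up to 2530) and Fabp2 (2620 and 2270 CPM, others up to 3860) did not separate them. Mep1a (51.5 and 96.5 CPM) lay below the median of the others, 275 CPM. The others also carried small intestinal transcripts, with medians of 2720 CPM for Apoa1, 573 for Fabp2 and 487 for Sis. Over 139 genes that differ between the small intestinal het tumour and the other het tumours, the deviations of wt 1 and wt 2 from the other wt tumours correlated with that difference at 0.808 and 0.917, and those of the 10 other wt and hom tumours at -0.485 to 0.526, which is consistent with a site other than the labelled large intestine. Carry-over of normal small intestinal mucosa would leave the Fabp6 of the tumour in place, and the higher Fabp6 level of wt 1 and wt 2 was 0.955% of the median of the other wt tumours, 6.90% without wt 3 or without wt 6. As it was 17.9% of the level in wt 4, carry-over stays open. Position along the intestine in all tumours, as a graded difference, stays open, and no tumour site was verified.

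In hom against wt, 2277 genes had an unadjusted p under 0.05 where 713.6 are expected, with 1341 without wt 4, 1443 without hom 6 and 3535 without wt 1 and wt 2. Removing GC content and length trends left 2240 genes and a Gata4 covariate left 2229, so neither accounts for the whole excess. Chance cannot be excluded, as 11 of 100 splits of the 12 tumours gave as many genes, up to 3992. A structure of the tumours that runs across genotypes may therefore account for the excess as well as the Macrod2 genotype.

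Splits of the same tumours were also drawn for the other counts, 100 for each comparison with the real one included. At least 1 gene was called in 4 of 100 splits for hom against wt, 4 for hom against het and 2 for carriers against wt. A count of at least 1 was thus rare, but the 1 gene called in each real split was Macrod2, whose loss defines the genotypes. The splits therefore do not exclude chance for any other gene. Macrod2 by itself was tested by the exact permutations of its CPM given in the Results, and not by these splits. No splits were drawn for the alternative fits that called 0 genes in these comparisons. These were both fits of RPKM, in which Macrod2 was not tested, and several others. For hom against het they were those with the block or the compared genotypes alone. For carriers they were those with the block, with het and hom merged or without wt 1 and wt 2. In the fit of the report the real count was 1 in each of these comparisons, and the highest of the others was 763, 1 and 8 genes. For hom against wt, splits with 763 and 631 genes point to a structure of the tumours, whose source was not tested. For het against wt the real count was 0, so all 100 splits gave as many, up to 168. Gene lists past the camera threshold were as many in 72 of 100 splits for het against wt (real 13, highest other 25), 81 for hom against wt (12, 27), 47 for hom against het (14, 22) and 82 for carriers against wt (12, 27), so chance cannot be excluded for any of these counts.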
